A study of Solenopsis invicta with 4 samples.

How the data were processed

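Total RNA of whole medium workers was extracted with Trizol and sequenced on an Illumina instrument from cDNA primed with oligo-dT, per the labels' protocols. There were 4 libraries, 1 at each of 10, 20, 30 and 40 °C. Groups were taken from the sample labels. Trimmomatic 0.38, FastQC 0.11.7, Bowtie 1.1.2 and RSEM are named in the submitters' processing notes, which give no version for RSEM. The assembler, annotation databases' versions and genome build were not given in the sources used here.

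Each of the 3 deposited tables sets 1 temperature against 30 °C and holds, per the file headers, read counts, FPKM values, log2 normalized values, a mean per group, a fold change, a log2 CPM, and raw and adjusted p-values for each contig, with annotation. The estimated counts deposited by the authors were whole numbers in every listed contig, and no rounding was needed. The log2 normalized values deposited by the authors equal log2(CPM + 1) with a scaled library size that is constant within a library. The FPKM values deposited by the authors follow a different scaling, by total reads. The fold changes and p-values in the authors' deposited tables come from the authors' own comparison and are used here to describe the lists. The tables list 4596 contigs at 10 °C, 2953 at 20 °C and 4067 at 40 °C, with a smallest absolute fold of 2.36, 2.36 and 2.35 in the authors' deposited tables, so they are filtered lists. Of the table for 40 °C, 1 line was not analysed here. The adjusted and raw p-values in the authors' deposited tables imply 26997 contigs tested. Those p-values were matched within 1% for 100% of the listed contigs by an exact test in edgeR 4.0.16 with the dispersion fixed at 0.09, and no replicate enters them, so they are not printed for single genes.

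From these files a log2 ratio of CPM with a pseudocount of 1 was computed for each contig. Contigs with a mean of at least 1 CPM over the 2 libraries were counted when at least 2-fold different. A read was worth 0.0431 CPM at 20 °C and 0.0230 CPM at 40 °C, the libraries with the smallest and largest scaled sizes. These sizes do not rank sequencing depth. By the FPKM values, total reads relative to 30 °C were 0.943 at 20 °C and 0.793 at 40 °C. The ratio of each named contig has an exact Clopper-Pearson 95% interval from the counts of both libraries given the scaled library sizes. It covers counting error only, since reads without molecular identifiers are not independent molecules and no library was repeated. The 29 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. List members were found by protein description. A list with at least 5 counted members has its median log2 ratio, and the percentile of that median among 10000 random lists of listed contigs matched on deciles of mean expression.

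Named genes were taken per temperature from contigs with a protein name and at least 50 reads in the higher library, with 1 contig per description. They are the 10 largest rises and 10 largest falls in log2 ratio, up to 4 members of each list, and the most abundant heat shock members, up to 6 from each of the 2 heat shock lists. Abundance was ranked on the 2 libraries of a table, where the plan named all 4 libraries, because a table holds 2. Members taken from lists were not reduced to 1 contig per description. The text leaves out the values of some named genes, among them adenylate cyclase type 8, PDF receptor and trypsin-1 at 40 °C and abaecin at 20 °C, each with a printed value equal to a number in the plan. Contigs were matched to gene names through the annotation of assembly UNIL_Sinv_3.0, which matched 1936 of 2180 gene identifiers at 10 °C, 1187 of 1380 at 20 °C and 1811 of 2050 at 40 °C. No coordinates are given, because the authors' build is not named. Contigs whose best protein hit lies in a fungus, bacterium, rodent or virus were marked by the genus of that hit, which is a name in a database and can be wrong.

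The alternatives were pseudocounts of 0.1 and 5, no filter and a filter of 10 CPM, the FPKM scaling in place of the authors' scaling, a 4-fold limit, 1 contig per protein description, and 1.5-fold between extremes over temperature. Leaving out contigs of other organisms, every listed contig, and the authors' adjusted p were added after the data were seen. The ratio and interval formulas, written out again apart from the analysis code, were tested on simulated Poisson counts with 200 contigs changed 4-fold. Of those, 87.1% passed 2-fold in the 10 °C setting of 4596 contigs, 82.6% at 20 °C and 86.8% at 40 °C. Overlaps expected against the shared control were simulated 10 times, with means drawn from the listed contigs. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, SciPy 1.17.1, matplotlib 3.10.9 and R 4.3.3 were used.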

Results

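RNA was sequenced from whole medium workers of the red imported fire ant, Solenopsis invicta, after 24 h at 10, 20, 30 or 40 °C. The labels name 30 °C as the control, and the colonies had been kept at 25 °C. Each temperature had 1 library, so no value below has a replicate check, no test between groups was made, and every difference is one between 2 libraries. Intervals are exact 95% conditional binomial intervals and cover counting error only. The scaled library sizes behind the authors' values were 30024104 reads at 10 °C, 23204029 at 20 °C, 38277639 at 30 °C and 43393168 at 40 °C. The authors' deposited tables list the assembled contigs past a raw p limit of 0.05, so a contig missing from a list is not called unchanged here. Folds are ratios of CPM, the read counts scaled by the library sizes above, and log2 ratios carry a pseudocount of 1 CPM. Counts of list members are over all listed contigs, and list medians and percentiles over those with a mean of at least 1 CPM. List members all have a protein name, while the random lists also draw contigs without one. At 40 °C 584 contigs with a protein name were at least 2-fold higher and 319 lower, against 886 and 960 of all counted. At 10 °C the counts were 405 and 429 against 766 and 993, and at 20 °C 205 and 231 against 427 and 657. A high percentile can therefore come in part from having a protein name.

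The comparison of 40 with 30 °C asks which transcripts differed after a day of heat. Molecular chaperones stood higher at 40 °C. Heat shock protein 83 (LOC105204027), the cytosolic HSP90, was 10.8-fold (10.5 to 11.0, 88285 reads against 7243) higher, and its co-chaperone Aha1, the activator of 90 kDa heat shock protein ATPase (LOC105199399), was 10.1-fold (9.12 to 11.3, 4396 reads against 383) higher. The mitochondrial 60 kDa heat shock protein (LOC105200658) was 9.45-fold (8.94 to 10.0, 14137 reads against 1319) higher, and endoplasmin (LOC105192989), the HSP90 of the endoplasmic reticulum, was 7.91-fold (7.41 to 8.45, 9121 reads against 1017) higher. Contigs of 2 genes named heat shock 70 kDa protein cognate 4 were 6.77-fold (6.62 to 6.93, 61814 reads against 8050) higher for LOC105205549 and 4.75-fold (4.66 to 4.85, 58259 reads against 10814) higher for LOC105201936. Near-identical members of this family can share reads, so the split between them is uncertain. Among the 22 listed chaperones and co-chaperones, 20 were higher and 2 lower. Their median log2 ratio was 2.04, above all 10000 random lists of listed contigs matched on mean expression.

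**Figure D1:**
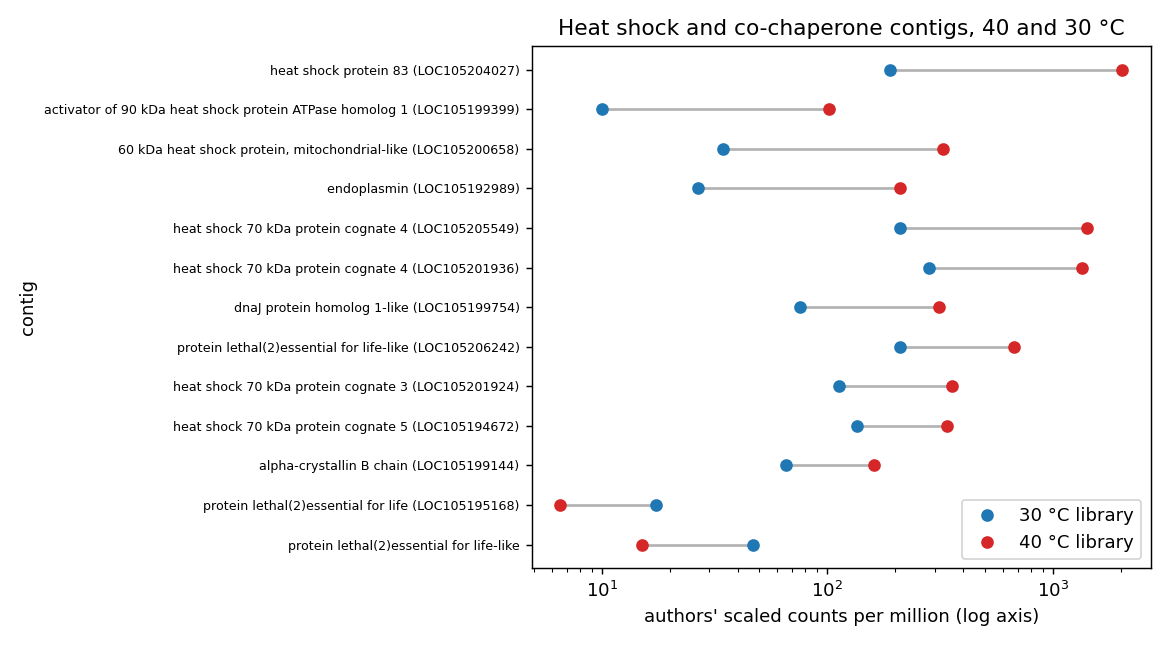
Authors' scaled CPM, on a log axis, for the named heat shock and co-chaperone contigs in the 30 °C library (blue) and the 40 °C library (red), 1 library each, with a grey line joining the 2 values of a contig. The contigs named lethal(2)essential for life lie on both sides, with LOC105206242 higher and LOC105195168 lower at 40 °C.

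The small heat shock proteins did not move as a group. Of 4 listed contigs, 2 were higher, namely LOC105206242 at 3.18-fold (3.10 to 3.26, 29061 reads against 8058) and an alpha-crystallin B chain (LOC105199144) at 2.46-fold (2.35 to 2.58, 6984 reads against 2503). The other 2 were lower, LOC105195168 at 2.66-fold (2.31 to 3.07, 284 reads against 667) and a contig named lethal(2)essential for life-like at 3.12-fold (2.85 to 3.41, 653 reads against 1795). DnaJ protein homolog 1-like (LOC105199754) was 4.15-fold (3.98 to 4.32, 13579 reads against 2889) higher. In the proteasome and ubiquitin list 22 of 30 contigs were higher, with a median log2 ratio of 1.30 at percentile 99.5 of the random lists. Its members included ubiquitin (LOC105199012), 3.62-fold (3.32 to 3.94, 2702 reads against 659) higher.

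Among contigs with a protein name, the largest rise in log2 ratio at 40 °C was that of a contig named Cep78 homolog (LOC105195170), 22.2-fold (21.5 to 22.9, 99435 reads against 3952) higher. A contig of the cyclic nucleotide phosphodiesterase 8A (LOC105195169) was 24.8-fold (20.8 to 29.8, 3683 reads against 131) higher. In the annotation of assembly UNIL_Sinv_3.0 both genes overlap. The phosphodiesterase gene also overlaps the small heat shock gene LOC105195168 and a further gene, LOC120357699. The reads of these genes therefore cannot be assigned with certainty. Some contigs of core histones, which package DNA, were higher at 40 °C. Histone H2B.3 (LOC105193510) was 172-fold (66.9 to 633, 780 reads against 4) higher, histone H2A (LOC105200468) 137-fold (58.3 to 422, 774 reads against 5) higher and histone H4 (LOC105193509) 37.0-fold (21.9 to 68.1, 587 reads against 14) higher. The H2A contig was also higher at 10 and 20 °C, at 3.33 and 0.690 CPM against 0.131 at 30 °C. Other listed histone contigs, with a fungal or bacterial best hit, were lower, and the replication and cell cycle list held 8 higher and 7 lower contigs, or 8 and 4 without contigs of other organisms. Its median log2 ratio was 2.07 at percentile 99.95, and at 10 °C it was 2.06 at percentile 99.7, with 8 higher and 3 lower. The 40 °C median rests on 8 counted contigs that range from -1.62 to 4.10. That at 10 °C rests on 5 that range from -1.25 to 2.21, and it changed sign with a filter of 10 CPM. The transporter MRP4-like (LOC105201723) was 11.4-fold (10.3 to 12.6, 5334 reads against 414) higher.

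The list of odorant-binding and chemosensory proteins, which carry odorants and pheromones in insect sensory organs, also holds chemosensory receptors. Its contigs were higher at 40 °C in 17 of 28 listed. Of the 19 with a mean of at least 1 CPM, 16 were at least 2-fold higher and 3 lower, and the median log2 ratio of 1.81 lay above all 10000 random lists. Ejaculatory bulb-specific protein 3 (LOC105196182), a chemosensory protein by family, was 10.5-fold (9.61 to 11.6, 5852 reads against 490) higher, and a related contig (LOC105196234) was 8.40-fold (7.98 to 8.84, 15711 reads against 1650) higher. An odorant-binding protein (LOC105194481) was 8.15-fold (7.59 to 8.76, 7687 reads against 832) higher and general odorant-binding protein 72 was 7.40-fold (6.43 to 8.55, 1854 reads against 221) higher. Detoxification genes were mixed. Cytochromes P450 were higher in 12 and lower in 10 contigs, with P450 6a20 (LOC105203261) 5.33-fold (5.05 to 5.64, 9098 reads against 1505) higher and P450 4C1-like (LOC105193888) 4.09-fold (3.38 to 4.97, 140 reads against 505) lower. The P450 4C1-like contig was also lower at 10 and 20 °C, at 2.76 and 3.66 CPM against 13.2 at 30 °C. UDP-glycosyltransferases, esterases and ABC transporters were higher in 14 of 19 contigs.

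Lists of lipid genes went both ways at 40 °C. The fatty acid synthesis list had 14 contigs higher and 8 lower, with a fatty acid synthase-like contig (LOC105206869) 43.1-fold (21.7 to 101, 391 reads against 8) higher. Of its contigs with a mean of at least 1 CPM, 7 were at least 2-fold higher and 3 lower. Among all contigs with a protein name those counts were 584 and 319. The lipase and beta-oxidation list had 5 contigs higher and 6 lower. The 4 listed fat body storage and transport contigs were higher, among them apolipophorins (LOC105200891), which carry lipid in the haemolymph, at 3.24-fold (3.15 to 3.34, 19729 reads against 5367). Trehalose-phosphate synthase (LOC105199129), which makes the blood sugar of insects, was 2.47-fold (2.36 to 2.58, 6950 reads against 2485) higher. Venom-named contigs were higher in 8 of 9. Digestive enzymes were lower in 9 of 12, at percentile 19.3 of the random lists, including anionic trypsin-2-like (LOC105207761) at 4.06-fold (3.45 to 4.80, 187 reads against 670).

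Of the largest falls at 40 °C, an excitatory amino acid transporter (LOC105207551), which removes glutamate, was 5.75-fold (5.59 to 5.91, 6152 reads against 31195) lower. The channel subunit unc-79 homolog (LOC105200842) was 5.36-fold (5.11 to 5.64, 1925 reads against 9107) lower. That contig was also lower at 10 and 20 °C, at 79.1 and 86.1 CPM against 238 at 30 °C. Protein takeout-like (LOC105203831) was 6.50-fold (5.96 to 7.11, 590 reads against 3385) lower. The neuronal list as fixed went both ways, with 6 contigs higher and 7 lower at percentile 20.5, and all 4 listed photoreceptor contigs were lower, including rhodopsin (LOC105199190) at 2.59-fold (2.43 to 2.75, 1462 reads against 3337). The oxidative phosphorylation list held 8 higher and 7 lower contigs, but 12 of its 15 contigs had a best protein hit in a rodent or fungus, and without those 0 were higher and 3 lower. Likewise 12 of the 15 ribosomal contigs had a fungal best hit.

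In all, 886 listed contigs with a mean of at least 1 CPM were at least 2-fold higher and 960 at least 2-fold lower at 40 °C. The split depends on the scaling and on the contigs counted. Among contigs with a protein name the counts were 584 higher and 319 lower, with 1 contig per protein description 531 and 276, and in the authors' deposited table, at an adjusted p under 0.05, 406 and 374. On the scale of the deposited FPKM columns log2 CPM ratios at 40 °C before the pseudocount are 0.52 larger, and less so with it in low contigs. The counts become 1060 higher and 467 lower, so the share of higher contigs goes from 48.0% to 69.4%. Only contigs listed on the authors' scaling were rescaled. Contigs that would pass 2-fold on the FPKM scale alone are missing, so these are not full counts on that scale.

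The comparison of 10 with 30 °C asks the same of cold. Venom-named contigs were higher at 10 °C in all 10 that were listed. Over the 6 counted ones the median log2 ratio was 1.55, at percentile 97.8 of the random lists. The rise was not particular to cold, since 6 of 7 listed at 20 °C and 8 of 9 at 40 °C were higher too. Low values in the 1 library at 30 °C cannot be told apart from an effect of temperature. Venom allergen 3 (LOC105199703), a major protein of fire ant venom, was 3.25-fold (3.19 to 3.32, 33215 reads against 13011) higher, and venom carboxylesterase-6 (LOC105204452) was 5.82-fold (5.38 to 6.30, 3525 reads against 772) higher. A further venom carboxylesterase-6-like contig (LOC105204441) was 369.7-fold (65.8 to 14653, 290 reads against 1) higher, on 1 read at 30 °C. The small heat shock gene LOC105195168, named lethal(2)essential for life, was 10.1-fold (7.58 to 13.6, 52 reads against 667) lower. Pyruvate carboxylase (LOC105192780), which feeds gluconeogenesis, was 36.2-fold (22.7 to 61.6, 511 reads against 18) higher and the pupal cuticle protein Edg-91-like (LOC105196226) was 17.2-fold (12.6 to 23.9, 593 reads against 44) higher.

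Cytochromes P450 were mostly lower at 10 °C, 21 against 11 higher, with a median log2 ratio of -1.25 at percentile 1.53. P450 2A13-like (LOC105206707) was 3.93-fold (3.57 to 4.34, 492 reads against 2465) lower and P450 6k1-like (LOC105204762) was 4.17-fold (3.51 to 4.98, 157 reads against 835) lower. Odorant-binding and chemosensory contigs were lower in 14 of 18, but their median log2 ratio of -1.08 lay at percentile 46.9 of the random lists. They included general odorant-binding protein 69a-like (LOC105195107) at 2.61-fold (2.53 to 2.70, 4362 reads against 14530). The higher members included odorant receptors 82a-like (LOC105204241) at 2.56-fold (2.19 to 2.99, 487 reads against 243) and 43a-like (LOC105202439) at 3.64-fold (2.67 to 5.03, 160 reads against 56).

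Genes of lipid synthesis went both ways at 10 °C, 11 higher and 11 lower. A fatty acid synthase-like contig (LOC105192918) was 4.62-fold (4.16 to 5.14, 414 reads against 2440) lower and acyl-CoA Delta(11) desaturase (LOC105200010) was 4.43-fold (3.83 to 5.14, 219 reads against 1237) lower. Hormone-sensitive lipase (LOC105198580), which releases stored fat, was 6.68-fold (5.04 to 8.98, 309 reads against 59) higher. The trehalose transporter Tret1-2 homolog (LOC105197048) was 16.7-fold (10.2 to 29.2, 223 reads against 17) higher, and a Tret1-like gene (LOC105193944) was 3.21-fold (2.97 to 3.47, 805 reads against 3296) lower. The mitochondrially encoded cytochrome c oxidase subunit I was 4.85-fold (4.77 to 4.93, 66232 reads against 17417) higher. Oxidative phosphorylation contigs were 14 higher and 4 lower, of which 8 had a best hit in a rodent or fungus. All 15 ribosomal contigs were higher, and 13 of them had a fungal best hit. The clock gene period (LOC105204533) was 4.22-fold (3.47 to 5.16, 122 reads against 656) lower, and aubergine (LOC105195576), of the piRNA pathway, was 3.04-fold (2.71 to 3.42, 372 reads against 1443) lower. The proteasome subunit 2-like contig (LOC105197079) was 13.0-fold (7.87 to 22.8, 173 reads against 17) higher in a list with 19 higher and 10 lower.

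Several of the largest differences at 10 °C were in contigs whose best protein hit lies in another organism, which need not be their origin. A contig named putative membrane protein, with a bacterial best hit, held 794720 reads at 10 °C against 24 at 30 °C. A polyprotein contig of Milolii virus was 12.4-fold (11.9 to 12.8, 3069 reads against 48344) lower. Of 53 contigs with a fungal best hit 51 were higher. In all, 766 contigs were at least 2-fold higher and 993 lower at 10 °C, and the FPKM scale moves log2 CPM ratios, before the pseudocount, by -0.02. The larger side depends on the contigs counted. Over every contig in the authors' deposited table the counts were 2599 higher and 1997 lower, at an adjusted p under 0.05 there 928 and 493, and at a 4-fold limit 123 and 59.

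**Figure D2:**
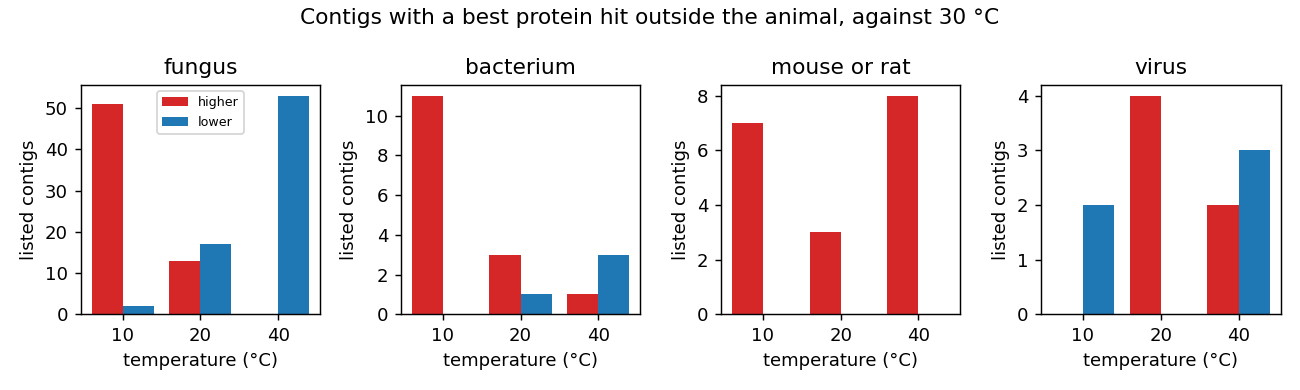
Number of contigs in the authors' lists whose best protein hit lies in a fungus, bacterium, mouse or rat, or virus, higher (red) or lower (blue) than at 30 °C at each temperature, with a separate axis per panel. Fungal contigs were mostly higher at 10 °C and all lower at 40 °C.

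**Figure D3:**
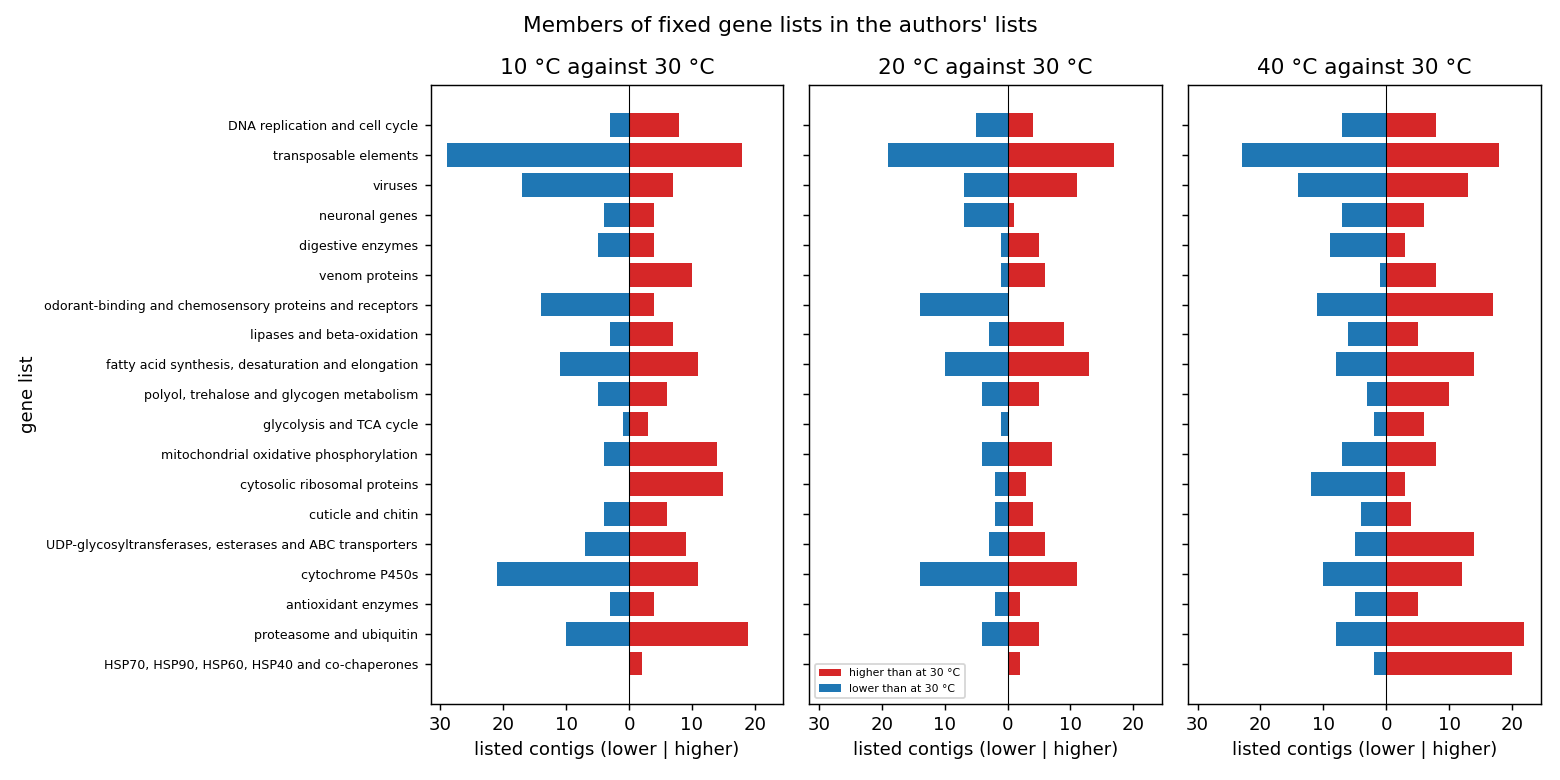
Number of contigs in the authors' lists that were higher (red, to the right) or lower (blue, to the left) than at 30 °C, for fixed gene lists with at least 8 listed contigs at 1 temperature or more, on the authors' scaling. Chemosensory contigs number 0 higher and 14 lower at 20 °C and 17 higher and 11 lower at 40 °C, and the ribosomal and oxidative phosphorylation bars include contigs of other organisms.

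The comparison of 20 with 30 °C covers mild cooling. The antimicrobial peptide hymenoptaecin (LOC105196795) was 28.8-fold (20.3 to 42.3, 577 reads against 33) higher, in an immune list with 2 contigs higher and 1 lower. Venom-named contigs were higher in 6 of 7, with venom allergen 2 (LOC105206474) 16.5-fold (15.1 to 18.1, 5203 reads against 521) higher and venom allergen 3 (LOC105199703) 4.73-fold (4.64 to 4.83, 37327 reads against 13011) higher. A contig named venom allergen 2-like, assigned to the same gene as venom allergen 2, was 5.09-fold (3.36 to 8.05, 25 reads against 210) lower. All 14 listed contigs of the odorant-binding and chemosensory list, receptors included, were lower, with a median log2 ratio of -1.62 at percentile 0.190. General odorant-binding protein lush was 5.20-fold (3.65 to 7.60, 35 reads against 300) lower and ejaculatory bulb-specific protein 3 (LOC105196182) was 4.43-fold (3.43 to 5.81, 67 reads against 490) lower.

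Some mitochondrially encoded respiratory transcripts were higher at 20 °C. Cytochrome c oxidase subunit I was 4.87-fold (4.78 to 4.95, 51368 reads against 17417) higher, NADH dehydrogenase subunit 4 4.84-fold (4.65 to 5.05, 8780 reads against 2990) higher, NADH dehydrogenase subunit 5 3.82-fold (3.69 to 3.95, 10503 reads against 4538) higher and cytochrome b 3.69-fold (3.61 to 3.78, 24893 reads against 11115) higher. The oxidative phosphorylation list had 7 contigs higher and 4 lower, 4 of them with a best hit in a rodent or fungus, at percentile 99.9. Without those contigs 5 were higher and 2 lower. Hormone-sensitive lipase (LOC105198580) was 9.56-fold (7.24 to 12.8, 342 reads against 59) higher. A fatty acid synthase-like contig (LOC105205072) was 3.40-fold (3.26 to 3.54, 2793 reads against 15661) lower, in a list with 13 higher and 10 lower. Neuronal contigs were lower in 7 of 8, at percentile 26.6 of the random lists, including synaptotagmin 1 (LOC105198222), a calcium sensor of transmitter release, at 3.33-fold (2.65 to 4.22, 89 reads against 489) and the FMRFamide-related neuropeptides (LOC105194687) at 2.86-fold (2.27 to 3.62, 91 reads against 429). Adenylate cyclase type 8 (LOC105208160), which makes cyclic AMP, was 5.14-fold (4.88 to 5.43, 1530 reads against 12983) lower and the sterol carrier NPC2 homolog (LOC105197297) was 6.63-fold (5.28 to 8.42, 82 reads against 897) lower. The adenylate cyclase contig was also lower than at 30 °C at 10 and 40 °C.

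In all, 427 contigs were at least 2-fold higher and 657 lower at 20 °C. The FPKM scale moves log2 CPM ratios at 20 °C, before the pseudocount, by -0.64. That leaves 144 higher and 771 lower, a share of higher contigs of 15.7% in place of 39.4%. Here too only contigs listed on the authors' scaling were rescaled, so the share is not that of a full count on the FPKM scale. The excess of lower contigs turned under other choices. Over every contig in the authors' deposited table the counts were 1546 higher and 1407 lower, at an adjusted p under 0.05 there 219 and 151, and at a 4-fold limit 41 and 27.

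Across temperatures, 410 contigs were at least 2-fold different the same way at 10 and 20 °C and 3 opposite ways. Between 10 and 40 °C the counts were 264 and 40, and between 20 and 40 °C they were 189 and 37. On the FPKM scaling the same-way count for 20 and 40 °C was lower, as given below with the other processing choices. The 26997 contigs the authors tested include those under 1 CPM, so the chance counts that follow are too low. Independent lists among them would share 12.1 higher and 24.2 lower contigs at 10 and 20 °C, where 150 and 260 were seen. For 10 and 40 °C they would share 25.1 and 35.3, against 67 and 197. For 20 and 40 °C they would share 14.0 and 23.4, against 28 and 161. Simulated unchanged libraries against the shared 30 °C library gave no called contig at all with Poisson noise, so the 0 shared contigs there decide nothing. With the dispersion behind the authors' p-values they gave 71.5, 67.3 and 72.1 contigs the same way for the 3 pairs. The simulated lists held 432, 446 and 413 contigs at 10, 20 and 40 °C, against 1759, 1084 and 1846 seen. The simulated and seen overlaps are therefore not directly comparable. With 1 control library no split of the control was possible, and part or all of the excess over independent lists may come from it. Compared directly, without the 30 °C library, 235 of the 264 contigs that differed the same way at 10 and 40 °C were within 2-fold of each other, and 385 of 410 at 10 and 20 °C. These contigs were chosen for lying on the same side of 1 control, so their closeness leaves open whether that control caused the overlap.

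Of the 302 contigs in all 3 lists, 126 were lower than at 30 °C at each other temperature and 117 higher at each. The 3 comparisons share the 30 °C library, so its noise alone can yield contigs extreme at 30 °C, and no simulated value stands beside these counts. With at least 2-fold between the extremes, 12 contigs were higher at each step from 10 to 40 °C and 17 lower at each step. These orders use the authors' scaling and were not taken on the FPKM scale. That scale moves log2 CPM ratios by -0.64 at 20 °C and -0.02 at 10 °C, enough to reverse small steps between them. General odorant-binding protein 72 was at 1.37 CPM at 10 °C, 1.51 at 20 °C, 5.77 at 30 °C and 42.7 at 40 °C. Synaptotagmin 1 (LOC105198222) followed the same order, with 3.30 CPM at 10 °C, 3.84 at 20 °C, 12.8 at 30 °C and 30.6 at 40 °C. In both contigs the step from 10 to 20 °C was small, and its direction is uncertain. The trehalose transporter Tret1-2 homolog (LOC105197048) went the other way, from 7.43 CPM at 10 °C to 0.0922 at 40 °C. Hymenoptaecin was highest at 20 °C, at 24.9 CPM, against 7.76 at 10 °C, 0.862 at 30 °C and 0.230 at 40 °C. Of the 6 chemosensory contigs in all 3 lists, 4 were lower at 10 and 20 °C and higher at 40 °C, and 2 were lower at all 3 temperatures. The former 4 were odorant-binding or chemosensory proteins. The latter 2 were the odorant receptors 67c-like (LOC105193016) and 43a-like (LOC105193356).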

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

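The tests on the Cep78 locus, on fungal contigs and on the 30 °C library were chosen after the results were seen, and the test of contig length was written before its result was seen. The rules for the overlapping small heat shock gene and for the 30 °C library were also reworded after a first run, because 1 library per temperature decides neither.

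Contigs at least 2-fold different in opposite ways at 2 temperatures numbered 3 for 10 and 20 °C, 40 for 10 and 40 °C and 37 for 20 and 40 °C, and these differences were not tested. Reads on contigs with a best hit in another organism lay outside the main measurement. They stood above the 30 °C library in some classes and below it in others. Listed contigs with a bacterial best hit held 1719765 reads at 10 °C and 132 at 20 °C. Of the former, 1718080 reads lay on 2 contigs that held 29 reads at 30 °C, which is 5.72% of the scaled library size. The other 9 contigs of this class held 1685 reads at 10 °C against 180, and the origin of the 2 was not tested. Listed contigs with a fungal best hit held 6478 reads at 10 °C against 889 at 30 °C, and 148 at 40 °C against 1663. At 20 °C they held 2242 against 1017, although 17 of 30 contigs were lower, and a single contig held 1003 of the reads against 38. Listed contigs with a mouse or rat best hit held 350 reads at 10 °C against 78 at 30 °C. Those listed at 20 °C held 45 against 7, and those at 40 °C 2339 against 123. All of them were higher than at 30 °C. Listed contigs with a virus best hit held 2389 reads at 20 °C against 558 at 30 °C. Viral contigs held 3075 reads at 10 °C against 48434 at 30 °C, and 16079 at 40 °C against 48706. A single contig held 13761 reads at 40 °C against 48344, and the contigs went both ways there, 2 higher and 3 lower. Listed contigs with a bacterial best hit also went both ways at 40 °C, 1 higher and 3 lower.

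Contigs named Cep78 homolog and phosphodiesterase 8A were higher at 40 °C, in overlapping genes beside the small heat shock gene lethal(2)essential for life. Reads of that gene counted on these contigs are a candidate cause, but its own contig had a log2 ratio of -1.29, and on 284 reads this decides nothing, since its reads could have been assigned elsewhere. A contig that joins more than the Cep78 gene is a candidate source of part of the signal, since its effective length lies at percentile 99.4 of the listed contigs. More transcription across the locus at 40 °C is a biological hypothesis, and 4 of 4 listed phosphodiesterase contigs were higher beyond counting error. With 1 library per temperature, that cannot be told apart from a difference between libraries.

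Contigs with a fungal best hit were lower at 40 °C in 53 of 53 and higher at 10 °C in 51 of 53. For the scaling between libraries, the upper quartile of their log2 CPM ratios at 40 °C was -2.88 and the 2 scalings differ by 0.52. Every contig listed at 40 °C differed by at least 2.35-fold, which is more than the 2 scalings differ. With all fungal contigs lower, the quartile had to lie beyond that difference, so it does not decide whether scaling plays a part. Different amounts of fungal RNA in the libraries are consistent with 100% of these contigs lying on the same side at 40 °C. Whether temperature or the workers sampled set that amount was not tested.

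The shares in this paragraph are over listed contigs with a mean of at least 1 CPM. Contigs with a nucleotide hit but no protein hit were lower than at 30 °C in 74.2% at 10 °C, 77.2% at 20 °C and 67.4% at 40 °C. Contigs with a protein hit were lower in 50.2%, 50.8% and 40.7%. Contigs with no hit were lower in 49.9%, 51.4% and 68.1%, so the excess at 40 °C was not particular to a nucleotide hit. At 40 °C contig length as the whole cause is argued against. In 2 of 3 equal classes of effective length the gap to contigs with a protein hit stayed over 5 percentage points beyond its 95% interval. Length was not examined at 10 and 20 °C. A property of the 30 °C library may be the cause, with a smallest excess of 24.0 percentage points over the 3 temperatures. It cannot be told apart from an effect of 30 °C itself, because 1 library stands for that temperature.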

How the results depend on the processing

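The contigs of other organisms, the whole authors' list and the authors' adjusted p were alternatives chosen after seeing the data. With a pseudocount of 5, the contigs higher numbered 183 at 10 °C, 102 at 20 °C and 325 at 40 °C. With a pseudocount of 5, the contigs lower numbered 278 at 10 °C, 205 at 20 °C and 407 at 40 °C. With a pseudocount of 5, median log2 ratios of the other sign were 0.00 for neuronal genes at 10 °C. With a pseudocount of 5, medians outside their interval were 0.38 for ribosomal at 10 °C, -0.94 for chemosensory at 20 °C, 0.88 for proteasome at 40 °C, 0.93 for UDP-glycosyltransferases at 40 °C, 0.76 for oxidative phosphorylation at 40 °C and 0.75 for polyol and trehalose at 40 °C. With a pseudocount of 0.1, median log2 ratios of the other sign were 0.03 for neuronal genes at 10 °C and 0.09 for fatty acid synthesis at 20 °C. With a pseudocount of 0.1, medians outside their interval were -1.59 for cytochrome P450s at 10 °C, 2.11 for ribosomal at 10 °C, -1.97 for viruses at 10 °C, -1.45 for transposable elements at 10 °C, 3.36 for DNA replication and cell cycle at 10 °C, 2.02 for proteasome at 20 °C, -1.98 for chemosensory at 20 °C, -1.28 for transposable elements at 20 °C, 1.49 for cytochrome P450s at 40 °C, 3.87 for oxidative phosphorylation at 40 °C, 1.94 for polyol and trehalose at 40 °C and -1.29 for transposable elements at 40 °C. With a filter of 10 CPM, the contigs higher numbered 112 at 10 °C, 71 at 20 °C and 268 at 40 °C. With a filter of 10 CPM, the contigs lower numbered 238 at 10 °C, 196 at 20 °C and 382 at 40 °C. With a filter of 10 CPM, the contigs different the same way numbered 91 at 10 and 20 °C, 79 at 10 and 40 °C and 71 at 20 and 40 °C. With a filter of 10 CPM, the contigs different opposite ways numbered 0 at 10 and 20 °C, 4 at 10 and 40 °C and 8 at 20 and 40 °C. With a filter of 10 CPM, median log2 ratios of the other sign were -1.22 for proteasome at 10 °C, -1.35 for UDP-glycosyltransferases at 10 °C, -1.42 for lipases and beta-oxidation at 10 °C, -1.25 for DNA replication and cell cycle at 10 °C, 0.15 for cytochrome P450s at 20 °C, -1.37 for cuticle and chitin at 20 °C and -1.22 for viruses at 40 °C. With a filter of 10 CPM, medians outside their interval were -2.79 for viruses at 10 °C, -1.99 for transposable elements at 10 °C, 2.31 for viruses at 20 °C, -1.29 for transposable elements at 20 °C, 1.67 for cytochrome P450s at 40 °C and -1.22 for transposable elements at 40 °C. At a 4-fold limit, the contigs higher numbered 123 at 10 °C, 41 at 20 °C and 122 at 40 °C. At a 4-fold limit, the contigs lower numbered 59 at 10 °C, 27 at 20 °C and 82 at 40 °C. At a 4-fold limit, the contigs different the same way numbered 21 at 10 and 20 °C, 8 at 10 and 40 °C and 5 at 20 and 40 °C. At a 4-fold limit, the contigs different opposite ways numbered 0 at 10 and 20 °C, 0 at 10 and 40 °C and 1 at 20 and 40 °C. With 1 contig per protein description, the contigs higher numbered 363 at 10 °C, 186 at 20 °C and 531 at 40 °C. With 1 contig per protein description, the contigs lower numbered 361 at 10 °C, 209 at 20 °C and 276 at 40 °C. With 1 contig per protein description, median log2 ratios of the other sign were -0.05 for lipases and beta-oxidation at 10 °C, 0.87 for transposable elements at 20 °C and -0.10 for viruses at 40 °C. Over every contig in the authors' deposited table, the contigs higher numbered 2599 at 10 °C, 1546 at 20 °C and 1899 at 40 °C. Over every contig in the authors' deposited table, the contigs lower numbered 1997 at 10 °C, 1407 at 20 °C and 2168 at 40 °C. At an adjusted p under 0.05 in the authors' deposited table, the contigs higher numbered 219 at 20 °C and 406 at 40 °C. At an adjusted p under 0.05 in the authors' deposited table, the contigs lower numbered 493 at 10 °C, 151 at 20 °C and 374 at 40 °C. On the FPKM scaling, the contigs higher numbered 144 at 20 °C. On the FPKM scaling, the contigs lower numbered 467 at 40 °C. On the FPKM scaling, the contigs different the same way numbered 115 at 20 and 40 °C. On the FPKM scaling, medians outside their interval were -2.01 for chemosensory at 20 °C, -1.64 for neuronal genes at 20 °C, 1.77 for proteasome at 40 °C, 1.49 for cytochrome P450s at 40 °C, 1.80 for polyol and trehalose at 40 °C and 1.73 for immune genes at 40 °C. Without a filter, median log2 ratios of the other sign were 0.48 for polyol and trehalose at 10 °C, 0.05 for fatty acid synthesis at 10 °C, 0.57 for fatty acid synthesis at 20 °C, 0.04 for antioxidant enzymes at 40 °C and -0.35 for viruses at 40 °C. Without a filter, medians outside their interval were 1.08 for proteasome at 40 °C and 0.75 for polyol and trehalose at 40 °C. Without contigs of other organisms, the contigs different opposite ways numbered 1 at 10 and 20 °C. With 1.5-fold between the extremes, 60 contigs were highest at 10 °C in another order, in place of 39. A higher fold limit or filter counts fewer contigs by construction. The FPKM scaling was applied to listed contigs alone, so its counts miss contigs that would pass 2-fold on that scale only. The setting of 1 contig per protein description also drops contigs without a protein name, and the adjusted p also drops the filter and the fold limit, so more than 1 choice changed there. For the other values the cause was not tested. Of the named contigs, values moved beyond the counting interval in 124 with a pseudocount of 0.1, 232 with a pseudocount of 5 and 130 on the FPKM scaling. None changed direction, but none could have. A pseudocount keeps the sign of a ratio, and the FPKM shifts are smaller than the smallest listed fold. The medians that turned sign belong to lists whose members went both ways. TMM and median-of-ratios scaling were not run, because the tables hold listed contigs alone. No paired analysis was possible because each temperature has 1 library. Depth limits contigs near 1 CPM, where the pseudocount sets much of the ratio.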

Other observations

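Hormone signalling contigs were 4 higher and 1 lower at 40 °C, 4 and 1 at 10 °C, and 2 and 1 at 20 °C. The genes named next are the higher ones at 40 °C. Juvenile hormone acid O-methyltransferase (LOC105205338), which makes juvenile hormone, was 5.65-fold (4.98 to 6.43, 1807 reads against 282) higher than at 30 °C, and a juvenile hormone-binding protein-like contig (LOC105203826) was 9.97-fold (6.67 to 15.5, 294 reads against 26) higher. Ecdysone-induced protein 74EF was 6.01-fold (4.82 to 7.57, 627 reads against 92) higher and the insulin-like peptide receptor (LOC105195102) 5.15-fold (4.14 to 6.47, 561 reads against 96) higher. Germline contigs went both ways at 10 °C, 3 higher and 3 lower. At 40 °C the germline genes piwi-like protein 1 (LOC105202009) and vasa (LOC105193214) were 2.86-fold (2.51 to 3.27, 962 reads against 297) and 5.76-fold (3.33 to 10.7, 98 reads against 15) higher. The acetylcholine receptor subunit alpha-2-like (LOC105203848) was higher at 7.92-fold (5.99 to 10.7, 494 reads against 55). The TRP channel A5 (LOC105204584), of a family that senses temperature, was 2.82-fold (2.52 to 3.17, 420 reads against 1046) lower.

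The RNA1 polyprotein contig of a picorna-like virus was 6.66-fold (5.74 to 7.75, 892 reads against 221) higher at 20 °C and 6.49-fold (5.64 to 7.50, 1626 reads against 221) higher at 40 °C. A histone H2A contig (LOC105200468) that was higher at 40 °C was also 25.5-fold (10.6 to 80.2, 100 reads against 5) higher at 10 °C, and histone H4 (LOC105193509) 12.8-fold (7.40 to 24.1, 141 reads against 14) higher. Immune genes at 40 °C were higher in 5 of 6 contigs, at percentile 82.1 of the random lists, with lysozyme 2-like 3.46-fold (3.16 to 3.79, 2298 reads against 586) higher. Transposable element contigs went both ways at each temperature, with 18 higher and 29 lower at 10 °C, 17 and 19 at 20 °C, and 18 and 23 at 40 °C.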
